A study of Mus musculus with 36 samples.

How the data were processed

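The values came from a series of 36 RNA sequencing libraries, 1 per mouse, and each mouse is a replicate per the labels. Per the labels' protocols, RNA was extracted with NucleoSpin RNA XS columns, and 10 ng was reverse transcribed with oligo(dT) primers (SMARTer Ultra Low). The cDNA was sheared (Covaris), made into libraries (Ovation Ultralow) with 13 to 15 cycles of PCR and sequenced as 101 bp paired reads on an Illumina HiSeq instrument. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned to mm10 with STAR and counted with featureCounts of the Subread package. Versions and the strand setting of the counting are not given in the sources used here, so values of antisense or overlapping genes are uncertain. Raw reads were not used here, and the depth of each library is unknown from the file.

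The authors deposited a table of 11337 genes by 36 libraries in RPKM, with no zeros and values from 0.00144 to 10500, together with the authors' correlation coefficient of each gene with Ccnd1, a score. The value times the exon length in kb summed to 958293 to 1204774 per library, near the total that an RPKM scale implies. Of the gene identifiers 11335 were found in GENCODE M21, which gave the mm10 positions, and 5 symbols occurred in 2 lines each. The centred log2 matrix had rank 29 where 35 is the largest possible. After 6 merged groups the residual rank was 24 where 30 was expected, which gives 6 removed directions. The removal is read from the values and its method is not given in the sources used here.

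Comparisons, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The planned count-based test could not be run on adjusted RPKM values and was replaced by limma on log2 values without a pseudocount. Linear models with 1 mean per group were fitted within each cohort, and over all 36 libraries for the difference of the age effects. Moderated statistics used eBayes with trend and robust settings, and p values were adjusted by Benjamini-Hochberg over the 11337 genes, with calls at an adjusted p under 0.05. The deposited scale was kept, and median-of-ratios scaling (RLE) served as an alternative. The threshold planned as 5 CPM became 5 RPKM.

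Genes named by size were the 6 largest increases and 6 largest decreases among called genes with a mean of at least 5 RPKM, with every test library on the same side of the control mean, leaving out clone and gene model names. Where none passed, the 3 genes with the lowest p were named as not passing. In each list up to 2 called genes in each direction were chosen by lowest p, and opposed genes were chosen by lowest p for the wheel, up to 6 in each direction.

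The 39 gene lists fixed beforehand, of which 890 of 972 genes were found, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 39 lists. Lists for keratinocyte and for B and plasma cell genes were added after the values were seen. Ccnd1 was tested by exact permutation of group labels. Correlations across genes were tested by permutation of labels and set against simulated unchanged groups with the same directions removed. Chance counts came from up to 100 splits of the libraries of each comparison into groups of the same sizes, the real grouping being 1 of them. Because the values were adjusted beside the real grouping, such permutations do not treat it like other groupings. In simulated unchanged groups, limma gave an unadjusted p under 0.05 less often than nominal for KO (2.14% of genes) and HET (2.48%). The same held for age in the wheel (4.16%) and Ccnd1 cohorts (0.582%). It was more often for the wheel in old (6.05%) and young mice (5.78%), their difference (6.15%) and KO against HET (6.52%). For the correlations of the age effect with KO and between cohorts, permutation favoured the real labels. Outlying libraries within groups were looked for with a Dixon test. Software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 for figures.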

Results

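Gene expression was measured by polyA RNA sequencing in skeletal muscle stem cells (MuSCs, the satellite cells that regenerate muscle fibres) sorted from hindlimbs of 36 male mice of 3 or 18 months, with 1 library per mouse. In the wheel cohort of 21 mice the cage held a running wheel that was either locked or free to turn for 3 weeks, and MuSCs were sorted by surface markers (VCAM positive, without CD31, CD45 or Sca1). It comprised 7 old and 6 young libraries with a locked wheel and 5 old and 3 young libraries with a free wheel. In the Ccnd1 cohort of 15 mice, tamoxifen induced Cre recombinase in Pax7-expressing cells that carried 2 intact copies of Ccnd1 (WT), 1 floxed copy (HET) or 2 floxed copies (KO), and YFP-positive cells were sorted 6 weeks later. It comprised 3 young WT, 4 young HET, 5 young KO and 3 old WT libraries.

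The deposited values covered 11337 genes on a scale of RPKM (reads per kb of gene, scaled to library size). Their sum per library ranged from 273800 to 351000 with a median of 313750, and 10430 to 10610 genes exceeded 1 RPKM in each library. The 50 most abundant genes took 24.13% to 28.94% of the sum. The labels' protocols give 20 to 40 M reads per library, but the depth of each library is unknown, since the values keep no counts, and so no counting interval is given. The log2 values had lost 6 directions of variation across the libraries, beside a model of 6 groups in which the controls of both cohorts were merged. As a result young WT and young locked-wheel libraries, and likewise old WT and old locked-wheel libraries, differed by less than chance would give, with 0 of 11337 genes at an unadjusted p under 0.05 by limma against 567 expected. The 2 cohorts are therefore not independent measurements of age.

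Ccnd1 encodes cyclin D1, which drives G1 progression with Cdk4 and Cdk6 (ENSMUSG00000070348, mm10 chromosome 7, 144929931 to 144939925, minus strand). In young mice its level was 11.7 ± 1.4 RPKM (SD, n = 3) in WT, 7.18 ± 0.723 (n = 4) in HET and 2.71 ± 0.495 (n = 5) in KO libraries, in the order of the genotype labels. It was 7.52 ± 1.44 (n = 3) in old WT libraries. In the wheel cohort the level was 11.3 ± 1.85 (n = 6) in young mice with a locked wheel and 7.72 ± 1.32 (n = 7) in old mice with a locked wheel. With a free wheel it was 17.1 ± 2.25 (n = 3) in young and 18.3 ± 3.69 (n = 5) in old mice. The sources used here do not give the floxed exons, so the remaining level in KO libraries can include reads from exons that were not deleted.

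**Figure D1:**
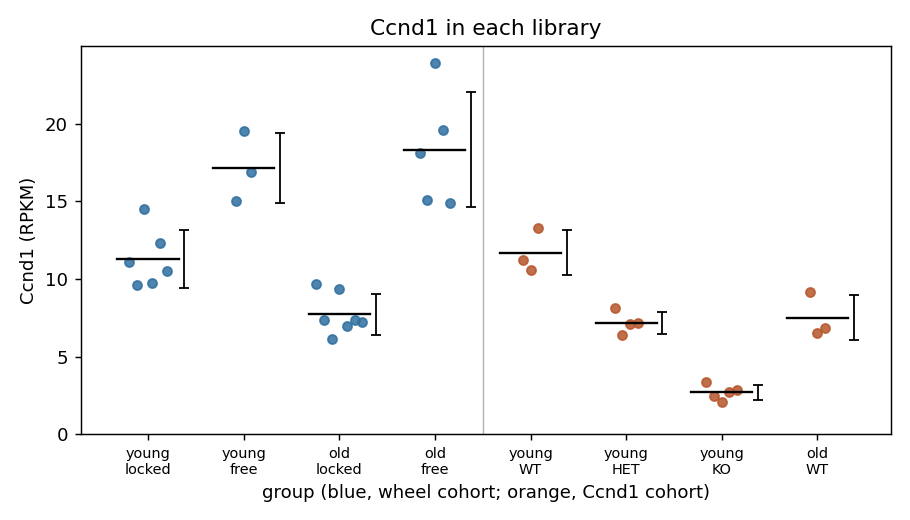
Ccnd1 level in RPKM (vertical axis) in each of the 36 libraries (points) of the 8 groups (horizontal axis), with bars for the group mean and SD. Old mice with a free wheel lay at 18.3 ± 3.69 against 7.72 ± 1.32 with a locked wheel, and KO libraries lay lowest at 2.71 ± 0.495.

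Tests of log2 Ccnd1 were two-sided exact permutation tests, adjusted by Benjamini-Hochberg over the 9 comparisons. The free wheel raised Ccnd1 in old mice by 1.24 (exact permutation p = 0.00126, the smallest that the test allows, adjusted p = 0.0113). In young mice it raised Ccnd1 by 0.61 (exact permutation p = 0.0119, also the smallest, adjusted p = 0.0268). Limma over all genes did not call the increase in young mice (adjusted p = 0.064). The difference between the increases was 0.63 and did not pass (exact permutation p = 0.192, adjusted p = 0.216). Ccnd1 fell by 0.55 with age in the wheel cohort (exact permutation p = 0.0035, adjusted p = 0.0158). In the Ccnd1 cohort the age difference was -0.65, and 3 against 3 libraries allow no exact permutation p below the observed 0.1, while limma over all genes called it (adjusted p = 0.021). KO lay 2.12 below WT (exact permutation p = 0.0179, adjusted p = 0.0322) and HET 0.70 below WT (p = 0.0286, adjusted p = 0.0429). KO lay 1.42 below HET (exact permutation p = 0.00794, adjusted p = 0.0238). Each is the smallest p the group sizes allow. The difference between the cohorts' age effects on Ccnd1 was 0.10 (exact permutation p = 0.801), but 89.4% of this contrast lay in the directions missing from the values, so the test cannot show whether they differ.

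The age comparison in the wheel cohort set 7 old against 6 young libraries with a locked wheel. Col1a1, a chain of type I collagen (mm10 chromosome 11, 94936224 to 94953042), was 6.15-fold lower in old MuSCs, at 22 ± 5.46 against 146 ± 77.5 RPKM (SD), with a log2 change of -2.62 ± 0.24 (SE, adjusted p = 2.3e-07). Igf1, which encodes a growth factor for muscle, was 3.33-fold lower (log2 -1.73 ± 0.14) and the tachykinin gene Tac4 was 5-fold lower (log2 -2.32 ± 0.19). Ly6k, a Ly6 family surface protein, was 4.98-fold higher at 10.9 ± 3.3 against 2.23 ± 0.875 RPKM (log2 2.32 ± 0.24, adjusted p = 6.1e-07). The thyrotropin receptor gene Tshr rose 3.57-fold (log2 1.84 ± 0.17), the neurotrophic factor gene Gdnf 3.38-fold (log2 1.76 ± 0.13) and the eosinophil chemokine gene Ccl11 3.38-fold (log2 1.76 ± 0.19). The other genes with the largest changes were Cytl1 and Rnf180, which rose 3.93-fold and 3.37-fold, and Rerg, Ttyh1 and Tubb4a, which were 3.79-fold, 3.43-fold and 3.11-fold lower.

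Of 32 ribosome biogenesis and translation factor genes, 27 rose with age and 1 fell (29 and 1 when adjusted over the list alone). Nop16 (0.82 ± 0.07) and Polr1c (0.62 ± 0.06) rose, while the elongation factor gene Eef2 fell (-0.51 ± 0.12). Camera gave this list an adjusted p = 1.47e-13, and an adjusted p = 0.15 with an estimated correlation. Of 32 interferon response and MHC class I genes, 24 rose and 1 fell (26 and 3 adjusted over the list alone). B2m rose by 0.67 ± 0.07 and Rtp4 by 1.1 ± 0.14 (list camera adjusted p = 1.24e-07, and adjusted p = 0.406 with an estimated correlation). Cytosolic ribosomal protein genes rose in 23 of 48 cases (26 adjusted over the list alone), including Rps15 at 0.63 ± 0.07 (camera adjusted p = 2.53e-06, and adjusted p = 0.529 with an estimated correlation). Antioxidant and NRF2 genes rose in 14 and fell in 2 of 23 cases, the same counts adjusted over the list alone. Gclc, which makes glutathione, rose by 0.88 ± 0.10 (list camera adjusted p = 0.000168, and adjusted p = 0.179 with an estimated correlation). Of 25 NF-kB and inflammation genes, 12 rose and 2 fell, the same adjusted over the list alone. Nfkb1 rose by 1.03 ± 0.12 and the cytokine gene Il6 by 1.12 ± 0.14 (list camera adjusted p = 0.0157, and adjusted p = 0.459 with an estimated correlation). Nuclear oxidative phosphorylation genes rose in 19 and fell in 1 of 43 cases (21 and 1 adjusted over the list alone), and heat shock and proteasome genes in 10 and 2 of 29 (11 and 2). Their camera adjusted p values were 0.000907 and 0.0385, and adjusted p = 0.529 with an estimated correlation for both.

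Extracellular matrix genes fell in 20 and rose in 4 of 40 cases (22 and 5 adjusted over the list alone). Col3a1 changed by -1.08 ± 0.10 and the crosslinking enzyme gene Lox by 0.64 ± 0.11 (list camera adjusted p = 4.99e-05, and adjusted p = 0.179 with an estimated correlation). Cholesterol biosynthesis genes fell in 16 of 24 cases (17 adjusted over the list alone). The synthase gene Hmgcs1 lay at -0.87 ± 0.14 (list camera adjusted p = 4.99e-05, and adjusted p = 0.459 with an estimated correlation). Of 26 S and G2/M cell cycle genes, 15 fell and 4 rose, the same adjusted over the list alone. The mitotic kinesin gene Kif11 lay at -1.54 ± 0.22 and the cyclin gene Ccnb2 at -1.20 ± 0.16 (list camera adjusted p = 0.00123, and adjusted p = 0.406 with an estimated correlation). Of 31 immediate early genes, which respond to cell dissociation, 15 fell and 1 rose (17 and 2 adjusted over the list alone). Egr2 changed by -0.93 ± 0.14 and Fosl1 by 1.04 ± 0.10 (list camera adjusted p = 0.00114, and adjusted p = 0.406 with an estimated correlation). Satellite cell identity genes fell in 9 and rose in 1 of 22 cases (10 and 1 adjusted over the list alone). Fgfr4 changed by -0.71 ± 0.09, Itga7 by -0.69 ± 0.09 and Cd34 by 0.42 ± 0.09 (list camera adjusted p = 0.0138, and adjusted p = 0.459 with an estimated correlation). Markers of mature myofibres, which the sort should exclude, fell in 7 of 15 cases (9 adjusted over the list alone). Their mean was -1.06, with Actn3 at -1.53 ± 0.19 (list camera adjusted p = 0.000497, and adjusted p = 0.488 with an estimated correlation). Among other cell type markers, 8 of 22 epidermal keratinocyte genes, a list added after the values were seen, rose with a mean of 1.83 (camera p = 0.000448, and p = 0.0163 with an estimated correlation), although Krt14 itself reached at most 0.105 RPKM in this cohort. For this list old WT 2 of the other cohort had a mean log2 of 0.87, and old WT 1 and 3 had -2.95 and -2.47. Old locked-wheel libraries lay at -1.96 to -1.22. As the removed directions drew old WT and old locked-wheel libraries together, this rise cannot be told apart from the keratins of old WT 2.

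In all, limma called 4342 of 11337 genes for age, 2321 higher and 2021 lower, of which 218 and 203 changed over 2-fold. The 12 genes with the largest changes kept their calls when any of the 13 libraries was omitted. Such omissions act on the adjusted values and do not undo the removal of directions. An age effect simulated in the old libraries of this cohort alone kept 72.8% of its size once the same directions were removed. The changes above therefore depend in part on the WT libraries of the other cohort. For this and each later comparison of 2 groups, the naming rule itself required every test library to lie on the same side of the control mean.

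The wheel comparison in old mice asked what voluntary running changed in old MuSCs (5 free-wheel against 7 locked-wheel libraries). Myog, which encodes myogenin, a transcription factor of muscle differentiation (mm10 chromosome 1, 134289989 to 134292548), was 3.38-fold higher, at 32 ± 13.5 against 9.92 ± 4.75 RPKM (SD), with a log2 change of 1.76 ± 0.40 (SE, adjusted p = 0.015). Ccnd1 rose 2.36-fold (log2 1.24 ± 0.13, adjusted p = 4e-05), and the small matrix proteoglycan gene Bgn rose 2.18-fold (log2 1.13 ± 0.13, adjusted p = 4.6e-05). The collagen gene Col8a1 was 2.53-fold higher (27.9 ± 7 against 12.2 ± 6.06 RPKM), Lrrn1 2.29-fold and Lrrc17 1.94-fold. The chemokine genes Cxcl5, Cxcl12 and Ccl11 were 2.03-fold, 1.85-fold and 1.73-fold lower (log2 -1.02 ± 0.23, -0.89 ± 0.18 and -0.79 ± 0.20), and the endocytic adaptor gene Dab2 was 1.70-fold lower (log2 -0.77 ± 0.14). The complement gene C3 was 2.9-fold lower (3.31 ± 0.971 against 10 ± 4.09 RPKM, adjusted p = 0.041) and the vasopressin receptor gene Avpr1a 2.02-fold lower (adjusted p = 0.048).

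Extracellular matrix genes rose in 10 and fell in 1 of 40 cases with the free wheel in old mice (13 and 4 adjusted over the list alone), including Col3a1 at 0.88 ± 0.10 (camera adjusted p = 0.000142, and adjusted p = 0.162 with an estimated correlation). Of 12 myogenic differentiation genes, 3 rose, the same adjusted over the list alone. Chrna1, a subunit of the muscle acetylcholine receptor, rose by 0.58 ± 0.13 (list camera adjusted p = 0.0318, and adjusted p = 0.25 with an estimated correlation). S and G2/M cell cycle genes rose in 5 and fell in 1 of 26 cases (7 and 3 adjusted over the list alone). Ube2c changed by 1.66 ± 0.25, Kif11 by 1.52 ± 0.23 and the replication helicase gene Mcm4 by -0.52 ± 0.10 (list camera adjusted p = 0.0227, and adjusted p = 0.475 with an estimated correlation). In the same libraries the 17 haematopoietic markers had a mean log2 change of 0.42 with none called (camera adjusted p = 0.177). Nuclear oxidative phosphorylation genes rose in 2 of 43 cases (5 adjusted over the list alone), with a mean of 0.12 (camera adjusted p = 4.3e-05, and adjusted p = 0.498 with an estimated correlation). JAK/STAT genes fell in 4 of 19 cases (5 adjusted over the list alone) and NF-kB genes in 3 of 25 (3 adjusted over the list alone), with Il6 at -0.66 ± 0.15 on both lists and Nfkb1 at -0.57 ± 0.12. Camera gave these lists adjusted p values of 0.000142 and 0.00117, and adjusted p = 0.162 and 0.367 with an estimated correlation. Circadian clock genes fell in 6 and rose in 1 of 19 cases (8 and 1 adjusted over the list alone). Cry2 lay at -0.63 ± 0.12 and Nfil3 at -0.43 ± 0.09 (list camera adjusted p = 0.000142, and adjusted p = 0.162 with an estimated correlation). Ribosome biogenesis genes fell in 6 of 32 cases (8 fell and 1 rose adjusted over the list alone) and glucocorticoid target genes in 3 of 18 (5 fell and 1 rose), with Errfi1 of the latter at -0.42 ± 0.08. Their camera adjusted p values were 0.00218 and 0.0247, and adjusted p = 0.475 with an estimated correlation for both.

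Limma called 838 genes for the wheel in old mice, 464 higher and 374 lower. The count was 471 without old locked 4, 556 without old locked 5, 468 without old free 2 and 351 without old free 3. Of the 12 genes with the largest changes, 9 kept their calls in each omission, while C3 and Avpr1a lost theirs in 10 of 12 omissions each and Col8a1 lost it without old free 3.

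The wheel comparison in young mice set 3 free-wheel against 6 locked-wheel libraries. Ass1, the urea cycle enzyme argininosuccinate synthase, was 2.1-fold higher (log2 1.07 ± 0.15, SE, adjusted p = 0.0023), and Srxn1, which repairs oxidised peroxiredoxins, was 1.77-fold lower (log2 -0.82 ± 0.13, adjusted p = 0.0039). Col8a1 was 4.04-fold higher at 15.8 ± 4.44 against 3.95 ± 0.98 RPKM (SD, adjusted p = 0.019), and Lrrn1, Grap, Atp2a3 and Hist1h1c were 2.35-fold, 2.19-fold, 2.08-fold and 1.98-fold higher. The sialidase gene Neu2 was 2.4-fold lower (103 ± 36.3 against 250 ± 79.2 RPKM), the protein C receptor gene Procr was 2.02-fold lower (9.98 ± 0.719 against 20.3 ± 3.21 RPKM), and Cxcl5, Gal and Nnmt were 2.3-fold, 1.91-fold and 1.69-fold lower.

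S and G2/M cell cycle genes rose in 3 and fell in 1 of 26 cases with the free wheel in young mice (9 and 1 adjusted over the list alone). Ube2c rose by 1.63 ± 0.31 and the topoisomerase gene Top2a by 1.40 ± 0.28 (list camera adjusted p = 1.08e-05, and adjusted p = 0.257 with an estimated correlation). Haematopoietic markers had a mean of 0.37 there with none called (camera adjusted p = 0.155). Ribosome biogenesis genes had a mean of -0.19 with 0 of 32 called over all genes and 13 lower adjusted over the list alone (camera adjusted p = 5.59e-08, and adjusted p = 0.257 with an estimated correlation). Antioxidant genes fell in 4 of 23 cases (7 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00365), and Schwann cell markers fell in 1 of 12 (4 adjusted over the list alone, camera adjusted p = 0.00216), namely the myelin gene Mbp at -0.71 ± 0.13. Both had an adjusted p = 0.257 with an estimated correlation. Of 19 circadian genes Hlf alone fell, at -1.04 ± 0.24 (4 adjusted over the list alone, camera adjusted p = 0.034, and adjusted p = 0.478 with an estimated correlation). No member was called over all genes among 25 unfolded protein response, 11 mitochondrially encoded and 24 G1 cyclin and Rb/E2F genes, whose lists had means of -0.16, -0.22 and 0.16 (camera adjusted p = 0.0168, 0.0192 and 0.0463, and adjusted p = 0.561, 0.561 and 0.257 with an estimated correlation).

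Limma called 127 genes for the wheel in young mice, 46 higher and 81 lower. The count fell to 17 without young free 1 and 5 without young free 2, and was 196, 66, 205, 74, 60 and 67 without young locked 1 to 6 in turn. It was 22 in a fit of the 3 free-wheel and 6 locked-wheel libraries alone. Of the 12 genes with the largest changes only Ass1 and Srxn1 kept their calls in each omission, and the other 10 lost them without young free 1 and without young free 2.

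The difference of the wheel effects between old and young mice was tested directly. Nr2f6, an orphan nuclear receptor gene (mm10 chromosome 8, 71374123 to 71381960), was the only gene called of 11337 by limma, against 960 at an unadjusted p under 0.05. Its wheel effect was higher by 1.60 ± 0.21 on the log2 scale in old mice (SE, adjusted p = 0.0017). With the free wheel its level was 1.45 ± 0.409 RPKM (SD, n = 3) against 4 ± 0.591 (n = 6) in young mice, and 6.26 ± 0.769 (n = 5) against 5.82 ± 0.948 (n = 7) in old mice. Its mean lay under the level required for naming genes by size, so it was chosen after its values were seen. The genes with the next lowest p, S100a4 (2.35 ± 0.43, adjusted p = 0.11) and Ass1 (-1 ± 0.20, adjusted p = 0.15), did not pass. Camera called 12 lists for the difference, the strongest being glucocorticoid targets with a mean of -0.44 (adjusted p = 5.59e-05, and adjusted p = 0.307 with an estimated correlation). Nuclear oxidative phosphorylation had a mean of 0.12 (adjusted p = 8.62e-05, and adjusted p = 0.633 with an estimated correlation). None of the 12 had a member called over all genes. The count of genes was 2 without old locked 7, 2 without young locked 4 and 5 without young free 3.

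Genes that changed with age in the locked-wheel libraries and in the opposite direction with the free wheel in old mice were chosen by lowest p in the wheel comparison. Ccnd1 (-0.55 ± 0.13 with age and 1.24 ± 0.13 with the wheel), Col3a1 (-1.08 ± 0.10 and 0.88 ± 0.10), the matrix glycoprotein gene Sparc (-0.57 ± 0.09 and 0.80 ± 0.09), Lrrc17 (-0.52 ± 0.13 and 0.96 ± 0.14), Ube2c (-1.30 ± 0.24 and 1.66 ± 0.25) and Kif11 (-1.54 ± 0.22 and 1.52 ± 0.23) fell with age and rose with the wheel. The reverse held for Tuba4a (0.80 ± 0.09 and -0.55 ± 0.09), the scaffold gene Homer1 (0.42 ± 0.09 and -0.54 ± 0.10), Opa3 (0.38 ± 0.05 and -0.30 ± 0.05), the glutamine synthetase gene Glul (0.36 ± 0.06 and -0.36 ± 0.07), the angiogenic factor gene Vegfa (0.26 ± 0.07 and -0.42 ± 0.07) and Hnrnpa2b1 (0.18 ± 0.06 and -0.38 ± 0.06). In total 145 genes were lower with age and higher with the wheel, where independent lists of these sizes would share 83. Another 108 were higher with age and lower with the wheel, where 77 would be shared. In the same direction 53 were higher in both (95 from independent lists) and 61 lower in both (67). Both comparisons share the old locked-wheel libraries. Splitting those libraries between the comparisons gave shorter lists. Medians over 35 splits were 46 genes lower with age and higher with the wheel (29 from independent lists of those sizes) and 27 the other way (21). In the same direction the medians were 25 higher (33 from independent lists) and 28 lower in both (21).

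Across all 11337 genes, which are not independent replicates, the wheel effect in old mice had a Pearson correlation of -0.115 with the age effect. This was 1 of 4 such correlations, with Benjamini-Hochberg adjustment over the 4. Shared controls alone gave a simulated r of -0.4 and a covariance of -0.0149 against the observed -0.018, and with split controls the median r was 0.011 (range -0.118 to 0.079). A two-sided permutation of the wheel labels of the old mice, exact over 792 assignments, gave p = 0.558 (adjusted p = 0.744), with a median r of -0.186 under permutation. A reversal of the age effect over all genes was therefore not detected.

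The Ccnd1 KO comparison asked what loss of cyclin D1 changed in young MuSCs (5 KO against 3 WT libraries). Ccnd1 fell 4.36-fold (log2 -2.12 ± 0.15, SE, adjusted p = 6.4e-06). Single cell cycle genes that fell were Top2a at -2.21 ± 0.37 (adjusted p = 0.009) and the spindle gene Tpx2 at -1.76 ± 0.27 (adjusted p = 0.0076). Cdk2, the kinase of the G1 to S transition, lay at -0.54 ± 0.09 (adjusted p = 0.0082). Gdpd3, a lysophospholipase D gene (ENSMUSG00000030703, mm10 chromosome 7, 126766334 to 126775649), was 44.4-fold higher, at 13.8 ± 4.39 against 0.372 ± 0.288 RPKM (SD, adjusted p = 0.013). It lies 18.2 Mb from Ccnd1, and 3 of the 4 HET libraries were also high. The matrix gene Comp rose 2.81-fold (log2 1.49 ± 0.27), the neuropeptide gene Npy 2.65-fold (1.41 ± 0.25) and Procr 2.48-fold, at 52.9 ± 8.95 against 22.5 ± 9.45 RPKM, while Thbs4 and Rbp7 were 2.95-fold and 2.79-fold higher, each with an adjusted p = 0.046. The imprinted CDK inhibitor gene Cdkn1c was 2.16-fold lower (log2 -1.11 ± 0.25), and Scd2, Tubb2b, Sox11 and the lamin gene Lmnb2 were 1.89-fold, 1.82-fold, 1.78-fold and 1.73-fold lower.

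**Figure D2:**
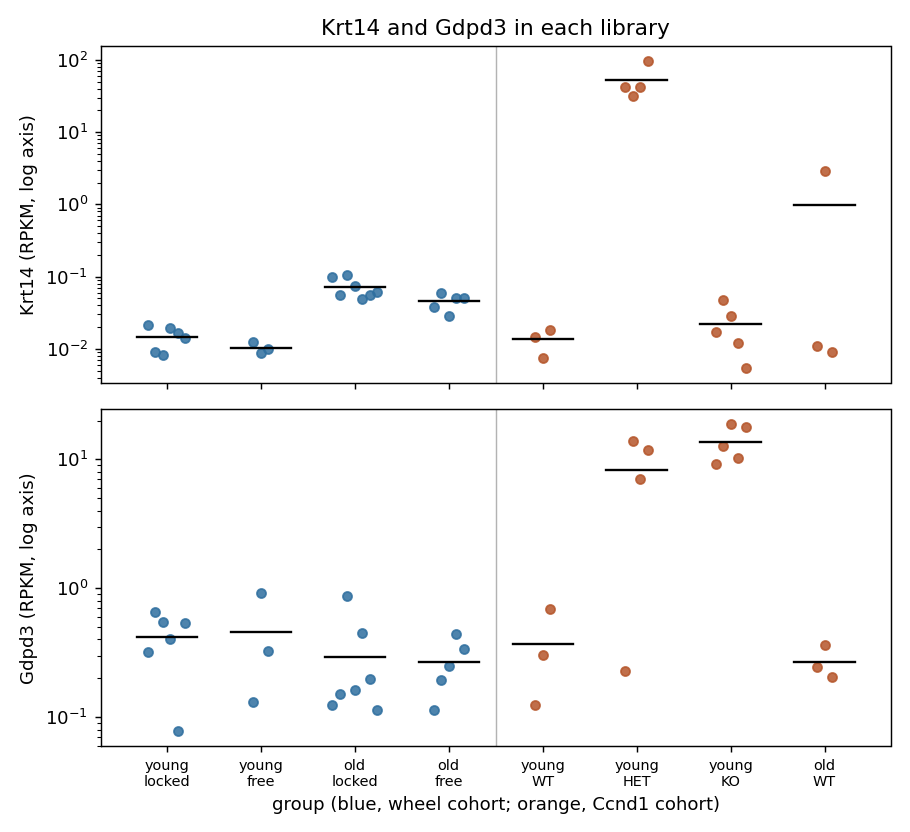
Levels of Krt14 and Gdpd3 in RPKM on a log axis (vertical) in each library (points) of the 8 groups (horizontal). Krt14 lay at 31.9 to 95.8 in the HET libraries and at 2.92 in old WT 2, and Gdpd3 lay at 9.15 to 18.7 in the KO libraries and at no more than 0.915 outside the KO and HET groups.

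Of 26 S and G2/M cell cycle genes, 10 fell in KO libraries and none rose, the same adjusted over the list alone (camera adjusted p = 3.07e-07), and this was the only list of the comparison still called with an estimated correlation (adjusted p = 0.0233). G1 cyclin, CDK inhibitor and Rb/E2F genes fell in 4 and rose in 1 of 24 cases (5 and 3 adjusted over the list alone). Ccnd2, another D-type cyclin gene, rose by 0.50 ± 0.12 (list camera adjusted p = 0.0238, and adjusted p = 0.672 with an estimated correlation). Ribosome biogenesis genes rose in 11 of 32 cases (21 adjusted over the list alone). Pes1 rose by 0.42 ± 0.07 and Gar1 by 0.69 ± 0.13 (list camera adjusted p = 2.93e-08, and adjusted p = 0.544 with an estimated correlation). Ribosomal protein genes rose in 3 of 48 cases (3 adjusted over the list alone) and nuclear oxidative phosphorylation genes in 6 of 43 (13 rose and 1 fell adjusted over the list alone), with Cox5b at 0.47 ± 0.10. Camera gave them adjusted p values of 3.07e-07 and 0.00104, and adjusted p = 0.819 with an estimated correlation for both. Tenocyte markers, which include Comp and Cilp2 (1.07 ± 0.28), rose in 3 of 11 cases (6 adjusted over the list alone, camera adjusted p = 0.00104, and adjusted p = 0.805 with an estimated correlation). Myogenic differentiation genes fell in 2 of 12 cases (4 adjusted over the list alone), namely Chrna1 at -0.73 ± 0.17 and Actc1 at -1.52 ± 0.36, and imprinted genes in 1 of 19 (2 fell and 1 rose adjusted over the list alone). Their camera adjusted p values were 0.0159 and 0.0204, and adjusted p = 0.267 with an estimated correlation for both. Cholesterol biosynthesis, heat shock and proteasome, and mature myofibre lists had means of -0.29, 0.15 and -0.35, with 0, 1 and 0 members called over all genes and adjusted over the list alone (camera adjusted p = 0.00214, 0.0366 and 0.0442, and adjusted p = 0.819 with an estimated correlation for each). The myofibre call was lost under median-of-ratios scaling (RLE, adjusted p = 0.081).

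Limma called 793 genes for KO, 573 higher and 220 lower. With RLE scaling 697 genes were called, 426 higher and 271 lower, so the share of higher calls was 61.1% in place of 72.3%. The count was 116 without young WT 2, 98 without young WT 3, 478 without KO 1, 320 without KO 3 and 314 without KO 5, and 379 in a fit of the KO and WT libraries alone. Ccnd1, Top2a, Tpx2 and Cdk2 kept their calls in each omission, and the other genes named here as changed lost theirs without young WT 2, without young WT 3 or in either case.

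The HET comparison set 4 libraries with 1 floxed copy of Ccnd1 against 3 WT libraries. Pcdh18, a protocadherin gene (mm10 chromosome 3, 49743296 to 49757325), was 2.53-fold lower (log2 -1.34 ± 0.20, SE, adjusted p = 0.005). The Notch target Hes1 rose (1.21 ± 0.22, adjusted p = 0.012), as did the Notch ligand gene Dll4 (0.85 ± 0.14, adjusted p = 0.0073), Klf2 (1.00 ± 0.17) and the lipase inhibitor gene Angptl4 (1.47 ± 0.26), while the imprinted gene Ndn fell (-0.77 ± 0.13). Coch, Vgll3, Ankrd1, Cdkn1c and Cxcl14 were 2.26-fold, 2.2-fold, 2.17-fold, 2.09-fold and 2.06-fold lower. The largest increases were genes of epidermal keratinocytes, a cell type that the YFP sort would remove. Krt14, the basal keratinocyte keratin (mm10 chromosome 11, 100203162 to 100207548), lay at 53.1 ± 28.9 RPKM (SD) against 0.0136 ± 0.00552 in WT. Krt5, Krt15, Ly6d, Perp and Sfn rose by 10.83 ± 1.40, 8.46 ± 1.05, 4.85 ± 0.54, 3.29 ± 0.38 and 2.34 ± 0.40 on the log2 scale. Of 22 keratinocyte genes, a list added after the values were seen, 20 rose (22 adjusted over the list alone), with a mean of 6.03 (camera p = 6.01e-36, and p = 0.00161 with an estimated correlation).

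Among the lists fixed beforehand, camera called 3 in HET libraries, and none was called with an estimated correlation. NF-kB and inflammation genes rose in 2 of 25 cases (2 adjusted over the list alone), namely Il6 at 1.32 ± 0.25 and Lcn2 at 1.90 ± 0.48 (camera adjusted p = 0.00471, and adjusted p = 0.824 with an estimated correlation). Mural and smooth muscle markers rose in 1 of 16 cases (1 adjusted over the list alone), namely Cspg4 at 0.83 ± 0.21 (camera adjusted p = 0.00272, and adjusted p = 0.673 with an estimated correlation). Ribosomal protein genes had a mean of 0.24 with 0 of 48 called by limma over all genes or adjusted over the list alone (camera adjusted p = 1.13e-06, and adjusted p = 0.975 with an estimated correlation). Of the S and G2/M genes, Tpx2 alone fell (-1.1 ± 0.28), and the list was not called (camera adjusted p = 0.238). The satellite cell transcription factor genes Pax7 (-0.49 ± 0.13, adjusted p = 0.042) and Myf5 (-0.95 ± 0.26, adjusted p = 0.046) fell, but lost their calls in 6 and 7 of the 7 omissions and under RLE scaling, as did Tpx2 in 5.

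Limma called 611 genes for HET, 225 higher and 386 lower, and 578 without the keratinocyte genes. With RLE scaling 461 were called, 274 higher and 187 lower, so the share of higher calls was 59.4% in place of 36.8%. The count was 68 without young WT 2, 259 without young WT 3, 266 without HET 1, 198 without HET 2 and 157 without HET 4, and 300 in a fit of the HET and WT libraries alone. Of the 12 genes with the largest changes, 7 kept their calls in each omission, and Coch and Vgll3 lost theirs only without young WT 2. The list members Hes1, Dll4, Klf2, Angptl4 and Ndn also kept theirs, and Il6 lost its call without young WT 2.

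KO libraries were also compared with HET libraries (5 against 4), a comparison of floxed genotypes that shares no WT library. Angptl7, an angiopoietin-like gene of tendon and cornea, was 3.58-fold higher in KO (log2 1.84 ± 0.35, SE, adjusted p = 0.0093), and the transcriptional regulator gene Cited2 was 2.05-fold higher (1.03 ± 0.20). Ndn rose by 0.93 ± 0.11 (adjusted p = 0.00085) and the crosslinking enzyme gene Loxl1 by 0.88 ± 0.13. Neu2 was 1.95-fold higher (293 ± 60.3 against 152 ± 42.8 RPKM, SD), and Chad and Comp were 2.57-fold and 1.9-fold higher. Ccnd1 was 2.68-fold lower (log2 -1.42 ± 0.14). The keratinocyte genes fell in 21 of 22 cases (22 adjusted over the list alone), with Krt14, Krt5 and Krt15 at -11.46 ± 1.32, -9.98 ± 1.23 and -9.12 ± 0.93, and Serpinb2, Ly6d and Sfn at -4.82 ± 0.91, -3.45 ± 0.47 and -2.96 ± 0.35.

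Ribosome biogenesis genes were higher in KO than HET libraries in 19 of 32 cases (27 adjusted over the list alone). Pes1 lay at 0.47 ± 0.07 and Wdr43 at 0.55 ± 0.09 (list camera adjusted p = 2.78e-13, and adjusted p = 0.266 with an estimated correlation). S and G2/M cell cycle genes were lower in 3 of 26 cases (12 adjusted over the list alone), including Top2a at -1.53 ± 0.34, with a camera adjusted p = 2.27e-06 and an adjusted p = 0.0377 with an estimated correlation. Tenocyte markers were higher in 6 of 11 cases (8 adjusted over the list alone), with the cartilage matrix gene Cilp2 at 1.70 ± 0.26 (camera adjusted p = 9.12e-06, and adjusted p = 0.543 with an estimated correlation). Antioxidant genes were higher in 3 of 23 cases (8 adjusted over the list alone), with Srxn1 at 0.70 ± 0.16, and 2 of 25 p53 target genes were lower (2 adjusted over the list alone), namely Perp, which is also a keratinocyte gene, and Bbc3 at -0.54 ± 0.11. Their camera adjusted p values were 0.0171 and 0.00462, and adjusted p = 0.704 and 0.171 with an estimated correlation. Cholesterol biosynthesis genes had a mean of -0.21 with none of 24 called (camera adjusted p = 0.000271, and adjusted p = 0.65 with an estimated correlation). Nuclear oxidative phosphorylation genes, higher in 2 of 43 cases (3 adjusted over the list alone), and haematopoietic, mural and myofibre markers, with none called, were called by camera (adjusted p = 0.0134, 0.00254, 0.0165 and 0.0148, and adjusted p = 0.86, 0.704, 0.607 and 0.86 with an estimated correlation). These 4 calls were lost under RLE scaling (adjusted p = 0.0932, 0.0521, 0.0521 and 0.11).

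Limma called 685 genes between KO and HET, 584 higher and 101 lower in KO, and 626 without the keratinocyte genes. With RLE scaling 330 were called, 199 higher and 131 lower, so the share of higher calls was 60.3% in place of 85.3%. The count was 370 without HET 1, 265 without HET 3, 324 without HET 4, 397 without KO 3 and 438 without KO 5, and 327 in a fit of the KO and HET libraries alone. Of the 12 genes with the largest changes 9 kept their calls in each omission, while Chad and Comp lost theirs in 7 and 5 of 9 omissions and under RLE scaling, and Neu2 lost it without HET 1 or HET 3. Top2a lost its call without HET 1, HET 3 or HET 4, and Srxn1 without HET 1, HET 3 or KO 5 and under RLE scaling.

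The age comparison in the Ccnd1 cohort set 3 old against 3 young WT libraries. An age effect simulated in old WT libraries alone kept 35.9% of its size once the same directions were removed. The changes below are therefore not an independent repeat of those in the wheel cohort. Ly6k was 4.86-fold higher (10.8 ± 3.95 against 2.24 ± 0.789 RPKM, SD, adjusted p = 0.0019), and Col1a1 was 5.4-fold lower (24.5 ± 10.2 against 137 ± 82.1 RPKM, adjusted p = 0.0045). Gdnf, Penk, Tshr and Ccl11 rose 3.49-fold, 3.61-fold, 3.41-fold and 3.16-fold. Igf1, Hist1h4d, Rerg, Ttyh1 and Tac4 were 3.78-fold, 4.73-fold, 4.83-fold, 3.29-fold and 5.39-fold lower. Perp rose 4.83-fold (log2 2.27 ± 0.41, SE), and keratinocyte genes rose in 4 of 22 cases (5 adjusted over the list alone, camera p = 2.32e-05, and p = 0.189 with an estimated correlation), with old WT 2 holding Krt14 at 2.92 RPKM.

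Ribosome biogenesis genes rose with age in 20 of 32 cases in the Ccnd1 cohort (24 adjusted over the list alone), with Pes1 at 0.74 ± 0.08 (camera adjusted p = 1.47e-12, and adjusted p = 0.456 with an estimated correlation). S and G2/M cell cycle genes fell in 9 and rose in 1 of 26 cases (12 and 1 adjusted over the list alone). Tpx2 lay at -1.62 ± 0.30 and Cdc20 at -1.39 ± 0.28 (list camera adjusted p = 0.00341, and adjusted p = 0.456 with an estimated correlation). Cholesterol biosynthesis genes fell in 10 of 24 cases (13 adjusted over the list alone), with Stard4 at -1.26 ± 0.19, and extracellular matrix genes fell in 9 and rose in 1 of 40 (15 and 3 adjusted over the list alone), with the metalloprotease gene Mmp14 at -0.71 ± 0.12. Ribosomal protein genes rose in 5 of 48 cases (3 adjusted over the list alone), nuclear oxidative phosphorylation genes rose in 6 and fell in 1 of 43 (6 and 1), antioxidant genes rose in 3 of 23 (7), heat shock and proteasome genes in 3 of 29 (3) and interferon genes in 1 of 32 (0). Immediate early genes fell in 4 and rose in 1 of 31 cases (5 and 1 adjusted over the list alone). Camera adjusted p was 2.23e-05 for the cholesterol, 0.00341 for the extracellular matrix, 4.84e-06 for the ribosomal protein, 0.00584 for the oxidative phosphorylation, 0.00695 for the antioxidant, 0.0166 for the heat shock, 0.0016 for the interferon and 0.0391 for the immediate early list, and each had an adjusted p = 0.727 with an estimated correlation.

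Limma called 1790 genes for age in the Ccnd1 cohort, 910 higher and 880 lower. The count was 1083 without young WT 2, 937 without young WT 3 and 873 without old WT 3. Of the 12 genes with the largest changes 10 kept their calls in each omission, while Tac4 lost its call without young WT 1, young WT 3 or old WT 1 and Tshr lost it without young WT 3.

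No gene differed in its age effect between the cohorts by limma (0 of 11337 called, with 0 at an unadjusted p under 0.05 against 567 expected), and Zdhhc9 (0.54 ± 0.33), Hmg20b (-0.48 ± 0.31) and Ptar1 (0.41 ± 0.26), which had the lowest p, did not pass. Camera called 4 lists for this difference. The cytosolic ribosomal proteins (mean -0.12, adjusted p = 9.92e-15) and mitochondrially encoded and cholesterol genes (-0.17 and 0.15, adjusted p = 0.000255 and 0.00202) had an adjusted p = 0.969 with an estimated correlation, and the myofibre markers (-0.69, adjusted p = 1.15e-12) had an adjusted p = 0.763. Of the contrast between the cohorts' age effects 89.4% lay in the directions missing from the values, so this file cannot show such a difference. Across genes, which are not independent replicates, the 2 age effects had a Pearson r of 0.945 and a covariance of 0.218, where unchanged groups simulated with the same directions removed gave 0.788 and 0.0271 (two-sided permutation of the age labels of the locked-wheel libraries over 1716 assignments, p = 0.00291, adjusted p = 0.0116 over the 4 correlations). The median r under permutation was 0.112, far below the simulated 0.788. This p therefore favours the real labels and is no test of agreement between the cohorts.

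The KO effect was set against the age and wheel effects, which share no library with it. Across the 11337 genes, which are not independent replicates, the KO effect had a Pearson r of 0.595 with the age effect in the wheel cohort, and the covariance was 0.11. Unchanged groups simulated with the same directions removed gave an r of 0.357 and a covariance of 0.0139. An exact two-sided permutation of the KO and WT labels over 56 assignments gave p = 0.0179, the smallest it allows, and an adjusted p = 0.0358 over the 4 correlations, with r from -0.554 to 0.595 under permutation. The median r under permutation was -0.022, where unchanged groups with the real labels gave 0.357. The permutation therefore favours the real labels, and its p cannot decide whether the effects correlate beyond the removal of directions. Without KO 2 or KO 3 the correlation was 0.589 or 0.572 and p = 0.0571 by exact permutation. With the wheel effect in old mice the KO effect had an r of -0.006 (exact permutation p = 0.964, adjusted p = 0.964, simulated r 0.02). Ribosome biogenesis genes had means of 0.44 with age and 0.31 in KO, and S and G2/M genes -0.59 and -0.72.

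**Figure D3:**
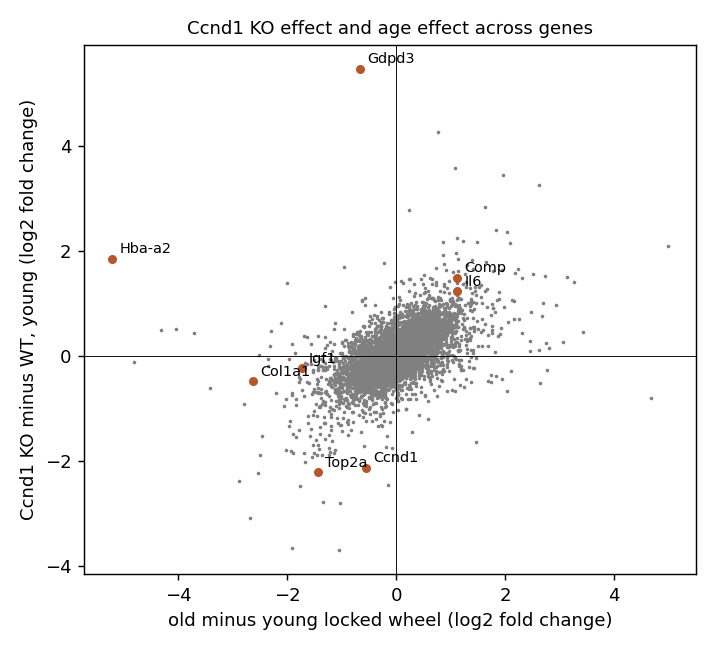
Log2 fold change of each of the 11337 genes for Ccnd1 KO against WT (vertical axis) and for old against young mice with a locked wheel (horizontal axis), with each point a gene. The cloud rises along the diagonal with a Pearson r of 0.595, against 0.357 for simulated unchanged groups. The covariance was 0.11, against 0.0139 for simulated unchanged groups.

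**Figure D4:**
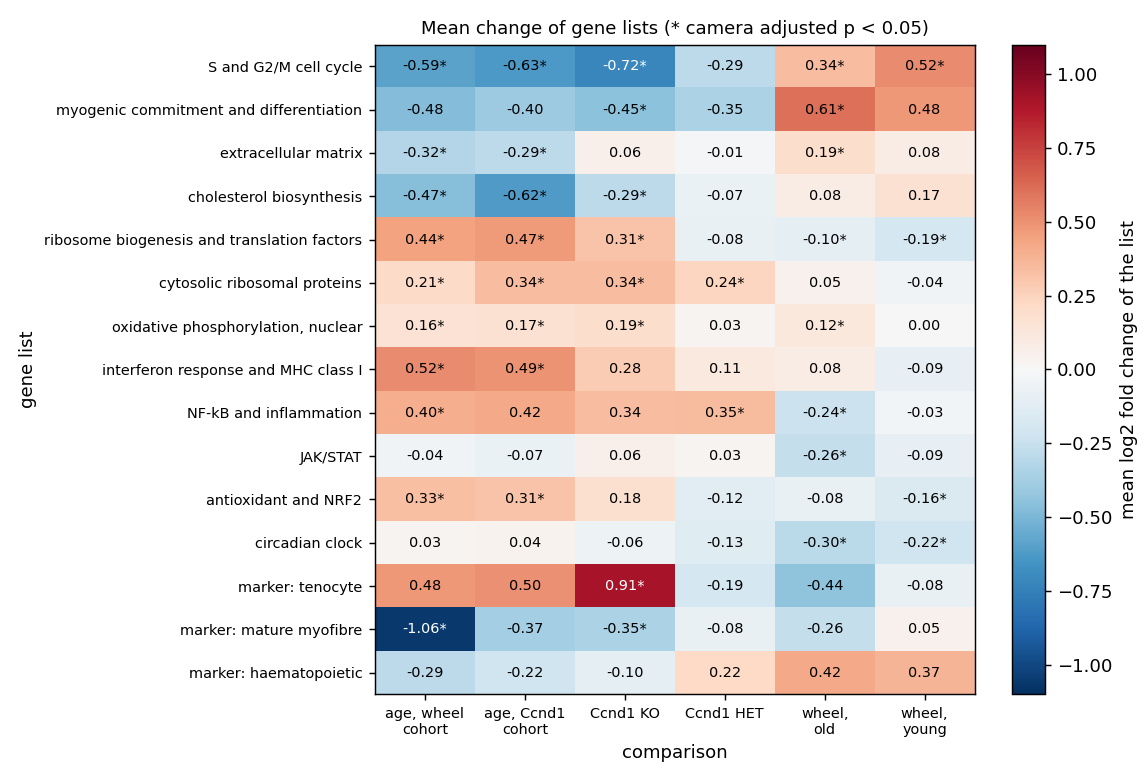
Mean log2 fold change of gene lists (vertical axis) in the comparisons (horizontal axis), printed in each cell and coloured by sign and size. Ribosome biogenesis genes had means of 0.44 with age in the wheel cohort and 0.31 in KO, and S and G2/M genes of -0.59 and -0.72.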

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

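The tests of Ccnd1 dose, of blood RNA and of the shared baseline below were chosen only after the result was seen, and the others were written before they were run. The keratinocyte genes lay above young WT by a mean log2 of 6.03 (SD 2.81) in the 4 HET libraries and 4.36 (SD 2.25) in old WT 2. These 2 differences had a Pearson r of 0.902 over the genes, but both subtract the same WT mean, and shuffled levels of old WT 2 gave a median r of 0.779 (95% of 10000 shuffles from 0.672 to 0.875, permutation p = 0.0045). The levels themselves had an r of 0.59, and the ratio of HET to old WT 2 ran from 1.03 to 16.6, so epidermal cells or RNA as the source stay open. In KO libraries the mean was 0.31 (SD 0.85), so a lower Ccnd1 dose is excluded as the cause.

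Hba-a2, an alpha globin gene (mm10 chromosome 11, 32296489 to 32297298), was at 4.37 ± 1.87 RPKM (SD, n = 6) in young and 0.141 ± 0.0874 (n = 7) in old mice with a locked wheel. Klk1, a kallikrein gene (mm10 chromosome 7, 44225360 to 44229618), was at 1.54 ± 0.652 against 0.109 ± 0.0959, and Klk1b21 and Klk1b27 fell by 4.31 ± 0.69 and 4.82 ± 1.1 on the log2 scale. Other erythroid genes had a median change of -0.01, with Alas2 at 0.73, Hba-a1 at 0.60 and the Hbb-b1 entries at -0.62 and -0.92, none called. Hba-a2 changed by -5.21, so these values argue against less blood RNA as the cause for Hba-a2. They do not bear on the Klk1 family, which is not on the erythroid list. Hba-a1 is near-identical to Hba-a2, so read assignment between them could differ. Strain variants between colonies could also give such genes, and 3 close pairs occurred among the 47 genes called beyond a log2 of 2 where random genes gave 1.87 on average (permutation p = 0.284), which cannot tell.

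DNA of the donor strain linked to the floxed Ccnd1 could raise or lower nearby genes. Of 185 genes within 20 Mb of Ccnd1 6.49% were called in KO libraries against 7% of the other 11149, a ratio of 0.927 (Fisher exact p = 0.885). The called genes as a set thus showed no excess near Ccnd1, although a modest effect of linkage cannot be ruled out. For single genes linkage stays open. Gdpd3 lay at 7 to 13.9 RPKM in 3 HET libraries and at 0.226 in 1. Nearer to Ccnd1, Cdkn1c (1.5 Mb, log2 -1.11 in KO and -1.06 in HET), Tssc4 (1.9 Mb, 0.48 and 0.69) and Ifitm1 (4 Mb, 1.07 and 1.52) were called in both floxed genotypes, and Tpcn2 (0.3 Mb, -0.66 and -0.56) in KO alone. Both genotypes were set against the same young WT libraries, so like changes in KO and HET can also come from those libraries.

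The libraries of each comparison were split into groups of the same sizes and tested by limma, with the real grouping counted as 1 of the splits. Leaving the real grouping aside, the highest count was 1822 in 100 splits for age in the wheel cohort (real 4342), 35 in 100 for the wheel in old mice (real 838) and 48 in 84 for the wheel in young mice (real 127). It was 46 in 56 for KO (real 793), 48 in 35 for HET (real 611), 22 in 100 for KO against HET (real 685) and 2 in 10 for age in the Ccnd1 cohort (real 1790), where 10 splits are too few for a share under 0.05. For the difference of the wheel effects 9 of 100 groupings, with the real one, called at least the real 1 gene (highest 128), so chance is not excluded. For the difference of the age effects the real count was 0 and the highest 1199.

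Of 80 groups of values tested, 6 held an outlier where 4 are expected by chance. The young WT, old WT and young free-wheel groups, with 3 libraries each, were not tested for outliers. Myog was at 17.1 RPKM in KO 1 (4.4 to 7.91 in the other KO libraries), Klk1 at 0.318 in old locked 6 (0.0375 to 0.107) and 0.273 in old free 3 (0.0719 to 0.11), and Col8a1 at 1.99 in young locked 4 (4.06 to 4.63). Old locked 5 had 10500 genes over 1 RPKM (10450 to 10470), and the 50 most abundant genes took 24.1% in KO 4 (27.2 to 28.3). A test of haematopoietic cells as the source of the cell cycle genes in free-wheel libraries was written beforehand and was not run. The wheel effect on Nr2f6 differed between ages by 1.60 on the log2 scale.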

How the results depend on the processing

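The merged-group model, pseudocounts and doubted libraries were chosen only after the result was seen. Counts moved over 1.5-fold as follows. For the wheel in young mice (127) weights gave 714, a replicate block 14, a 2-group fit 22 and merged groups with the removed directions 80. For the difference of the wheel effects (1) weights gave 5 and a pseudocount of 1 gave 2. The block sets libraries of the same replicate number together. Residuals of same-number KO and WT libraries had a mean correlation of -0.006, against 0.001 for other numbers, so no pairing was seen between them. For old locked and old free libraries the means were 0.113 (pairs from -0.148 to 0.302) and -0.019. In the other pairs of groups the same-number mean ran from -0.057 (old and young locked) to 0.053 (old and young WT). For KO (793) the block gave 1, the 2-group fit 379 and merged groups 1904. For HET (611) these were 179, 300 and 1407, and weights gave 1324. For KO against HET (685) RLE gave 330, the block 262 and the 2-group fit 327. For age in the Ccnd1 cohort (1790) merged groups gave 5111. This is the pooled age effect of both cohorts, the same fit as for age in the wheel cohort (4342). Merged groups likewise added young locked-wheel libraries to the controls of KO and HET. To the controls of the wheel in young mice they added young WT libraries. The merged counts thus answer a different comparison from that of 1 cohort. Called lists at an estimated correlation were 1 for KO, 1 for KO against HET and 0 elsewhere. With fry they were 24 for age in the wheel cohort, 5 for the wheel in young mice, KO, KO against HET and age in the Ccnd1 cohort, and 0 for both differences, and RLE left 6 for KO against HET. Hba-a2 with the wheel in young mice was 0.39 (not passing) and -0.257 with the block. Omitting 1 library gave 351 to 923 for the wheel in old mice, 5 to 205 in young mice, 1 to 5 for their difference, 98 to 938 for KO, 68 to 621 for HET, 265 to 743 for KO against HET and 873 to 1366 for age in the Ccnd1 cohort. The KO correlation with age was 0.501 to 0.611. The Ccnd1 change in HET was -0.768 to -0.609, with too few assignments left for the exact test. The other count tool and the unfiltered setting were not run.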

Other observations

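The share of covariance and the look at Jchain in this part were chosen only after the result was seen. The genes below are members of lists that camera did not call for age in the wheel cohort (7 old against 6 young libraries, log2 ± SE). They are single genes among the 4342 called of 11337 and stand for no change of their pathways. The TGF-beta targets Pmepa1 (0.95 ± 0.09) and Ctgf (1.02 ± 0.13), the ligand genes Wnt4 (1.04 ± 0.16) and Hgf (1.37 ± 0.22) and the autophagy receptor gene Sqstm1 (0.52 ± 0.07) rose. The Wnt receptor gene Fzd4 (-0.97 ± 0.09), the ERK phosphatase gene Dusp6 (-1.24 ± 0.14), the imprinted gene Mest (-1.13 ± 0.19), the Notch effector gene Rbpj (-0.47 ± 0.07) and the lysosomal gene Lamp2 (-0.45 ± 0.06) fell. Hes1 and Dll4 of the Notch pathway rose in KO (1.11 ± 0.21 and 0.63 ± 0.13, 5 against 3) as in HET libraries. KO and HET share their young WT controls, so these are not 2 independent results. The plasma cell gene Jchain rose with age by 4.67 ± 1.38 (adjusted p = 0.0106), with high levels in old locked 7 (8.08 RPKM) and old free 1 (11.1 RPKM). The added list of B and plasma cell genes had mean log2 levels of -1.725 to 2.339 in old locked-wheel libraries. In young locked-wheel libraries these were -2.658 to -0.577. Without old locked 7 and old free 1, limma called 4142 genes for age in the wheel cohort.

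Of the genes in the authors' deposited table, 853 had a coefficient with Ccnd1 over 0.5 and 692 under -0.5, led by Rpap1 (0.886) and Lrrc17 (0.872), with Vegfa at -0.793. A Pearson coefficient recomputed from the values had an r of 0.989 with it, and the largest difference was 0.19.

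Leaving out the 130 cell cycle, G1 and ribosome genes gave the KO and age effects an r of 0.59, which 1.15% of the genes could hardly move. Those genes held 2.92% of the covariance. Simulated unchanged groups already gave an r of 0.357, though with a covariance of 0.0139 against the observed 0.11. For this correlation the removal of the 6 directions favours the real labels, so part of it may come from the adjustment. Whether lower Ccnd1 contributes to the age pattern is left open. HET libraries had Ccnd1 at 7.18 RPKM, near the 7.72 of old mice with a locked wheel. Their ribosome biogenesis mean was -0.08 against WT where age gave 0.44. The median over all genes was itself -0.058 in HET against WT, and -0.004 under RLE scaling. The HET means of S and G2/M and myogenic genes, -0.29 and -0.35, were not called by camera. They had the sign of the age means of -0.59 and -0.48. HET libraries also held the keratinocyte genes. The wheel raised Ccnd1 in old mice to 18.3 RPKM, and its effect had an r of -0.006 with the KO effect, while S and G2/M means were -0.72 in KO and 0.34 with the wheel, and myogenic means -0.45 and 0.61.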
